A study of Mus musculus with 6 samples.

How the data were processed

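Gene expression was measured on 6 Affymetrix 3' expression arrays of total RNA from mouse primary embryonic mesenchymal cells, 48 h after retroviral transduction. In 3 samples the retrovirus carried ASPSCR1-TFE3, a fusion of the ASPSCR1 gene with the transcription factor gene TFE3, and in 3 it was the empty vector. Both vectors carry GFP behind an internal ribosome entry site, per the labels. Groups and replicate numbers were taken from the sample titles, which also name the limb. No label says whether the replicates came from separate embryos, cultures or transductions, so the p-values measure only the spread between these samples, which may be technical.

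The deposited values are on a log scale, taken here as log2 because the sources used here do not give the base. MAS5 is the only tool named in the submitters' processing notes, without a version. Normalisation between arrays and centring are not given in the sources used here. The table itself showed that the authors' values had been centred per probe set. Array medians lay between -0.02 and 0.01, values ran from -3.54 to 6.66, and none was missing. In 30.4% of the probe sets 1 value was the exact negative of another (within a relative tolerance of 1e-06), and never more than 5 of the 6 values lay above 0. Centring on the median of 10 arrays would give such a pair in 33.3% of probe sets, so 0 is taken as a median over a larger set that includes 4 arrays not analysed here. The centring removes the absolute level of each probe set, so a value can be compared between arrays but not between genes, and signal over background is unknown. If the log base were not 2, the folds below would change and the calls would not.

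Of 45141 probe sets, 104 were controls. The platform annotation gave exactly 1 gene symbol for 28898, several for 551 and none for 15692. Symbols were updated through the Entrez ID to the mouse gene table of assembly GRCm38.p6, which held 28689 of the probe sets with 1 symbol. The value of a gene was the mean over its probe sets with exactly 1 symbol, which gave 17097 genes, 7180 of them with more than 1 probe set. Probe sets of 1 gene can disagree, and 69 genes had probe sets called in both directions.

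Groups were compared with limma (version 3.58.1, in R 4.3.3) by lmFit and eBayes over all 6 arrays, with no covariate. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The adjusted p-values of single genes given below come from this limma fit. An exact permutation test of 3 against 3 samples cannot give a p below 0.1, so none was used for single genes. Gene lists were tested with camera from the same package at a preset inter-gene correlation of 0.01, again with Benjamini-Hochberg adjustment, over 41 lists with at least 5 measured members. Camera with an estimated correlation and fry were run beside it. The 95% intervals of list means in the closing section come from a t test with equal variances on the mean of the list on each array. The lists were written from general knowledge, and 1056 of their 1172 distinct genes were matched. For each list the calls over all genes are given together with those adjusted over the list alone. Tables were prepared with Python 3.11.15, pandas 2.3.3 and data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9.

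The groups, the lists, the rule for named genes and the planned tests were fixed before the data were examined. The rule named Tfe3, Tfeb, Mitf, Tfec and Aspscr1. It also named the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap, leaving out symbols of clones and predicted genes. In each list it named up to 4 called members with the largest absolute difference. Members named because they moved against the rest of their list were chosen after their values were seen.

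The plan differed from what was run in 3 ways, because centred values carry no level. The plan had a filter on dim genes, the probe set with the highest mean per gene, and a variance trend over intensity. None of these can be computed as meant from centred values, so no filter and no trend were used and probe sets were averaged. These 3 settings had been planned as alternatives. They became the main choice after the table had been seen, when the genes with the largest differences were already known. Adding 16 before the logarithm and a stricter filter were not run for the same reason.

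The fit was tested on simulated data for this comparison, with 17097 genes of which 200 were changed by known amounts. It called 80% of the genes changed by 0.5 on the log2 scale, 98% of those changed by 1, 100% of those changed by 2 and 96% of those changed by -1. Of its 199 calls 12 were false. A list shifted by 0.3 was called, and so was 1 other list. Other lists can share members with the shifted one. Genes were drawn independently, so the simulation does not test the lists under correlation between genes. It also held no effect shared by a whole array, and far fewer genes were changed than were called in the data. Its share of false calls therefore need not hold for the real gene calls. Alternatives covered normalisation between arrays, the choice of probe sets, the variance model, array weights, the replicate number as a block, and each array left out in turn. After the data had been seen, alternatives were added for arrays whose spike-in controls stood apart. The number of arrays limits the precision.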

Results

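The data comprised 6 arrays, 3 from embryonic mesenchymal cells transduced with ASPSCR1-TFE3 and 3 from cells transduced with the empty vector. TFE3 belongs to the MiT/TFE family of transcription factors, which control lysosomal and pigment cell genes, and the fusion is the defining lesion of alveolar soft part sarcoma. The comparison asks which transcripts differ 48 h after the fusion is introduced. Expression is given as deposited log2 values centred per probe set, so a value of 0 is no absolute level. The median SD of a gene between arrays was 0.07 in the ASPSCR1-TFE3 group and 0.07 in the empty vector group (n = 3 each). Arrays of the ASPSCR1-TFE3 group correlated with each other across genes at r = 0.84 to 0.91, and those of the empty vector group at 0.66 to 0.79. Genes are not independent replicates.

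Aqp3, a water and glycerol channel, showed the largest rise with ASPSCR1-TFE3, 49.0-fold, from -0.03 ± 0.02 to 5.58 ± 0.21 (mean ± SD, n = 3; log2 difference 5.62 ± 0.10 SE, adjusted p = 6.4e-08). Of the gene lists, 30 of 39 lysosomal hydrolases, 13 of 19 vacuolar ATPase subunits, 14 of 25 pigment cell genes, 17 of 19 cholesterol genes and 30 of 39 skeletal muscle markers rose. In contrast, 34 of 38 genes of G2 and mitosis, 27 of 46 fibrillar matrix genes and 17 of 26 matrix proteases and inhibitors fell. These 8 lists passed camera at the preset correlation, and had adjusted p = 0.0726 to 0.302 with an estimated correlation. The largest fall was that of Esm1, an endothelial proteoglycan, which fell 6.52-fold, from 1.46 ± 0.24 to -1.24 ± 0.21. In all, 2613 genes rose and 2434 fell out of 17097 tested, of which 432 rose and 73 fell at least 2-fold.

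After Aqp3, the largest rises were those of Synpr, a synaptic vesicle protein, by 4.34 ± 0.16 (log2 difference ± SE), and Cpeb1, a regulator of mRNA polyadenylation, by 3.92 ± 0.12. Nppb, the precursor of B-type natriuretic peptide, rose by 3.82 ± 0.08, and Blnk, a B cell signalling adaptor, by 3.69 ± 0.13. Fgfbp3 rose by 3.64 ± 0.20, the pyridoxal kinase gene Pdxk by 3.62 ± 0.10, and Elovl4, an elongase of very long chain fatty acids, by 3.46 ± 0.14. Trim63, a muscle ubiquitin ligase, rose by 3.38 ± 0.11, the unconventional myosin Myo7a by 3.24 ± 0.08, the amino acid transporter Slc6a15 by 3.17 ± 0.12 and the nuclear receptor Rorb by 3.11 ± 0.16. The adjusted p-values of these 11 genes ran from 9.1e-08 for Nppb to 6.1e-06 for Fgfbp3.

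Falls were smaller. Vgf, a secreted neuropeptide precursor, differed by -2.69 ± 0.13, the protease inhibitor Serpinb2 by -2.55 ± 0.13, thrombomodulin (Thbd) by -2.25 ± 0.10 and the urea transporter Slc14a1 by -2.24 ± 0.14. Lubricin (Prg4) differed by -2.08 ± 0.14, the growth factor Ereg by -1.96 ± 0.14, the chemokine Cxcl5 by -1.93 ± 0.12 and the noncoding Mir100hg by -1.92 ± 0.08. Pf4 differed by -1.83 ± 0.10, Ltbp2 by -1.82 ± 0.11 and the cartilage collagen Col2a1 by -1.78 ± 0.16. All of these passed the test, with adjusted p-values from 1.9e-06 for Mir100hg to 8.1e-05 for Col2a1. Serpinb2 did not pass under a variance trend over the mean deposited value (adjusted p = 0.0569).

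**Figure D1:**
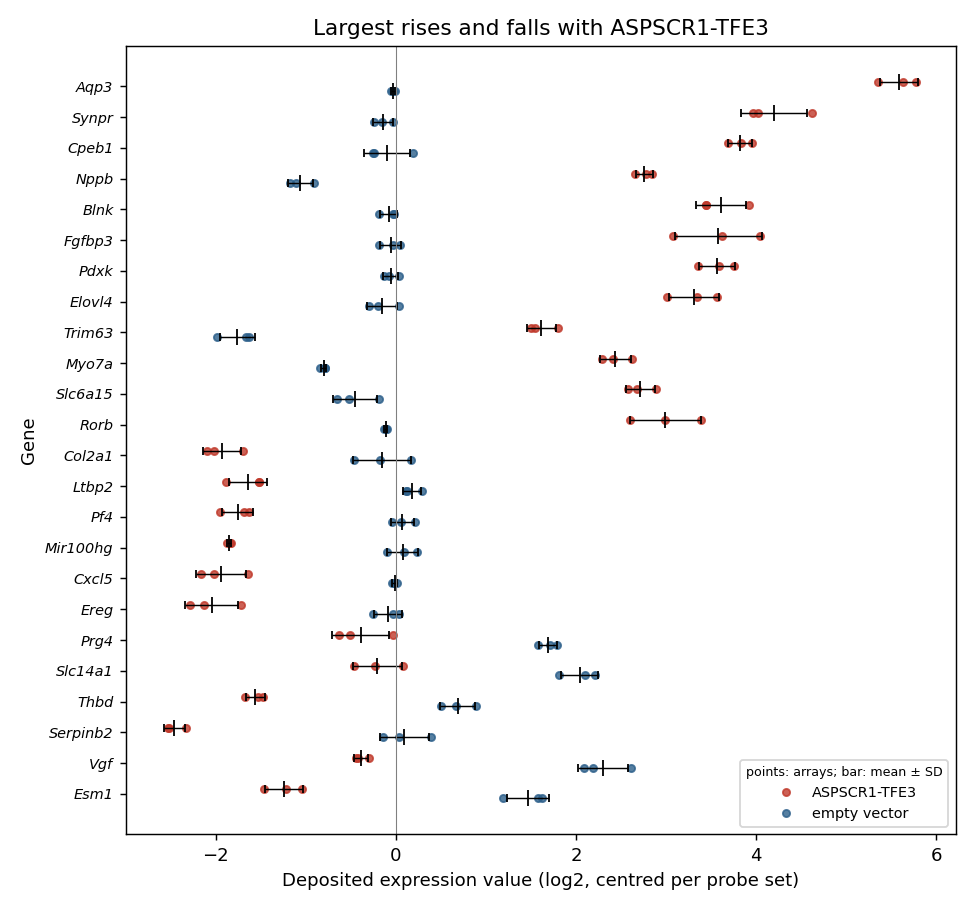
Deposited expression values (log2, centred per probe set) of the 12 genes with the largest rise and the 12 with the largest fall, with 1 point per array and bars for the mean ± SD of 3 arrays. The ASPSCR1-TFE3 arrays lie right of the empty vector arrays for the rises, up to a mean of 5.58 for Aqp3, and left of them for the falls.

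Endogenous Tfe3 fell by 0.61 ± 0.09 on the log2 scale (adjusted p = 0.00104), though it did not pass with the hybridisation spike-in level as a covariate (adjusted p = 0.0669). The difference was 0.10 ± 0.06 for Tfeb, 0.03 ± 0.08 for Mitf, 0.12 ± 0.08 for Tfec and 0.15 ± 0.08 for Aspscr1, and none of these 4 passed. The mouse probe sets need not read the fusion transcript, so they do not check the labels. The family list, with Aspscr1, thus had 0 members that rose and 1 that fell of 5, and 0 and 1 when adjusted over the list alone (camera adjusted p = 0.853).

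Lysosomal genes moved together. Of 39 lysosomal hydrolases 30 rose and 0 fell (33 and 1 when adjusted over the list alone), among them alpha-galactosidase A (Gla) by 2.60 ± 0.06, Dpp7 by 1.78 ± 0.10, arylsulfatase A (Arsa) by 1.27 ± 0.06 and cathepsin S (Ctss) by 1.20 ± 0.05. The list passed camera (adjusted p = 3.4e-15), with an adjusted p = 0.0726 with an estimated correlation. Of 25 lysosomal membrane proteins 19 rose and 0 fell (21 and 0 when adjusted over the list alone), including Ostm1 by 2.12 ± 0.07 and the cystine transporter Ctns by 1.58 ± 0.06, and Tmem192 by 1.44 ± 0.05. Camera gave an adjusted p = 1.4e-12, and adjusted p = 0.0956 with an estimated correlation. Of 19 subunits of the vacuolar ATPase, which acidifies the lysosome, 13 rose and 0 fell (14 and 0 when adjusted over the list alone). Atp6v1d rose by 1.72 ± 0.08 and Atp6v1h by 1.59 ± 0.07. The list had an adjusted p = 3e-08, and adjusted p = 0.103 with an estimated correlation. Macrophage and myeloid markers, from cells rich in lysosomes, were also higher in 19 of 30 cases (adjusted p = 0.103 with an estimated correlation).

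Among 21 regulators of amino acid sensing and mTORC1 at the lysosome, 11 rose and 1 fell, over all genes and adjusted over the list alone. Folliculin (Flcn) rose by 1.33 ± 0.06 and its partner Fnip2 by 1.86 ± 0.13, and the GTPase Rragd by 1.80 ± 0.07, although its 2 probe sets differed (0.31 and 3.29). The member that fell was Deptor (-0.25 ± 0.06), an inhibitor of mTOR. Camera gave an adjusted p = 4.1e-05, and adjusted p = 0.103 with an estimated correlation. Of 29 autophagy genes 14 rose and 2 fell (15 and 3 when adjusted over the list alone), with Uvrag higher by 1.22 ± 0.09 and Gabarapl1 by 0.98 ± 0.06, and Wipi1 (-0.31 ± 0.05) and Wipi2 (-0.22 ± 0.07) lower. This list had an adjusted p = 0.00216, and adjusted p = 0.121 with an estimated correlation. Without empty vector arrays 2 and 3, whose hybridisation spike-ins stood apart, 9 autophagy genes rose.

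Of 25 pigment cell and melanosome genes 14 rose and 0 fell, over all genes and adjusted over the list alone. Melanoregulin (Mreg) rose by 3.09 ± 0.11, the melanosome receptor Gpr143 by 2.29 ± 0.11, the organelle motor Myo5a by 2.11 ± 0.09 and the melanosome matrix protein Pmel by 1.82 ± 0.11. Camera gave an adjusted p = 3.7e-07, and adjusted p = 0.0726 with an estimated correlation. In the list of alveolar soft part sarcoma genes, 10 of 21 rose and 2 fell, over all genes and adjusted over the list alone. Prostaglandin D2 synthase (Ptgds) rose by 2.88 ± 0.11 and Uap1l1 by 1.57 ± 0.07, beside Trim63 and Rragd, while Aurkb (-0.38 ± 0.08) and Tfe3 fell. The set test gave an adjusted p = 0.000227, and adjusted p = 0.119 with an estimated correlation. Some genes of this list may be known from these same samples, in which case its direction is not independent evidence.

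Cholesterol synthesis and uptake genes rose in 17 of 19 cases and fell in 1, with the same counts adjusted over the list alone. Insig1, a sterol-regulated inhibitor of the pathway, rose by 2.24 ± 0.07, Mvd by 1.22 ± 0.09, and Lss and Sc5d by 1.03 ± 0.14 and 1.03 ± 0.06. Hmgcs1, which makes HMG-CoA, differed by -0.61 ± 0.12. The camera test of the list gave an adjusted p = 3e-09, and adjusted p = 0.119 with an estimated correlation. Of 34 unfolded protein response and ATF4 target genes 14 rose and 2 fell, over all genes and adjusted over the list alone, including the hormone Fgf21 by 1.73 ± 0.17, Cth by 1.37 ± 0.10 and Nupr1 by 1.21 ± 0.08. Aldh18a1 (-0.53 ± 0.08) and Pdia4 (-0.56 ± 0.06) fell. The adjusted p was 0.00524, and adjusted p = 0.273 with an estimated correlation. Without ASPSCR1-TFE3 arrays 2 and 3, whose poly-A spike-ins stood apart, 7 of these genes rose.

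Of 20 glycolysis genes 8 rose and 1 fell, over all genes and adjusted over the list alone. Hexokinase 2 (Hk2) rose by 2.92 ± 0.11 and the lactate transporter Slc16a1 by 0.86 ± 0.08, while another, Slc16a3, fell by 0.63 ± 0.14 but did not pass with either spike-in covariate or without arrays 2 and 3 of either group (adjusted p = 0.076 to 0.488). The adjusted p was 0.00847, with adjusted p = 0.314 with an estimated correlation, and the list did not pass without empty vector array 1 (adjusted p = 0.0811) or with the poly-A covariate (adjusted p = 0.123). Without empty vector arrays 2 and 3, 5 glycolysis genes and 6 hypoxia genes rose. Of 26 hypoxia response genes 11 rose and 4 fell (13 and 4 when adjusted over the list alone). Bhlhe40 rose by 1.53 ± 0.07 and Ndrg1 by 0.98 ± 0.15, while Vegfa (-0.44 ± 0.11), Adm (-0.81 ± 0.05), Lox (-0.27 ± 0.05) and the oxygen sensor Egln1 (-0.19 ± 0.06) fell. The adjusted p was 0.00847, with adjusted p = 0.467 with an estimated correlation, and the list did not pass without ASPSCR1-TFE3 arrays 2 and 3 (adjusted p = 0.106) or with the poly-A covariate (adjusted p = 0.186). Oxidative phosphorylation genes shifted by a small amount, with 16 of 56 higher and 0 lower, over all genes and adjusted over the list alone, and a mean log2 difference of 0.16. Uqcrfs1 rose by 0.41 ± 0.08, but did not pass under the 4 spike-in alternatives named for Slc16a3 (adjusted p = 0.0956 to 0.157). By camera the adjusted p was 1.3e-06, with adjusted p = 0.554 with an estimated correlation, and the list did not pass without ASPSCR1-TFE3 arrays 2 and 3 (adjusted p = 0.0843) or with the poly-A covariate (adjusted p = 0.152). The count was 7 without any 1 of ASPSCR1-TFE3 arrays 2 and 3 and empty vector arrays 2 and 3, 26 without ASPSCR1-TFE3 array 1, and 0 without arrays 2 and 3 of either group.

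Genes of G2 and mitosis fell. Of 38 measured, 34 were lower and 0 higher (38 and 0 when adjusted over the list alone), with the kinase Plk1 at -0.85 ± 0.09, the kinesin Kif20a at -0.77 ± 0.06, Ncapd2 at -0.73 ± 0.06 and Mki67 at -0.62 ± 0.08. Tested with camera, the list had an adjusted p = 3.4e-15, and adjusted p = 0.119 with an estimated correlation. Of 38 S phase and DNA replication genes 22 fell and 3 rose (23 and 5 when adjusted over the list alone). The polymerase gene Pole differed by -0.76 ± 0.05, Rrm2 by -0.68 ± 0.06 and Mcm6 by -0.60 ± 0.05. Against these, Chaf1b, a chromatin assembly factor, rose by 0.81 ± 0.06, with 1 of its 2 probe sets called. Ung rose by 0.57 ± 0.06 and Orc1 by 0.26 ± 0.06. For the list as a whole the adjusted p was 0.000106, and adjusted p = 0.302 with an estimated correlation. Without ASPSCR1-TFE3 arrays 2 and 3, 17 mitosis genes and 11 S phase genes fell, and without empty vector arrays 2 and 3, 13 S phase genes fell.

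The fibrillar matrix list fell, with 27 of 46 members lower and 2 higher (31 and 2 when adjusted over the list alone). The collagen gene Col1a2 differed by -1.38 ± 0.08 and Mfap5 by -1.02 ± 0.11, while elastin (Eln, 0.49 ± 0.05) and Col14a1 (0.25 ± 0.05) rose. For this list camera gave an adjusted p = 1.6e-07, and adjusted p = 0.302 with an estimated correlation. Col1a1 differed by -0.98 ± 0.23 and did not pass without empty vector array 3 (adjusted p = 0.0512), without empty vector arrays 2 and 3 (adjusted p = 0.223) or with the hybridisation covariate (adjusted p = 0.58). Of 26 matrix proteases and inhibitors 17 fell and 0 rose (17 and 2 when adjusted over the list alone), among them Mmp9 (-1.58 ± 0.14), Mmp13 (-1.29 ± 0.12) and Mmp3 (-1.27 ± 0.11). The list passed camera with an adjusted p of 2.9e-06, and adjusted p = 0.0726 with an estimated correlation. Without empty vector arrays 2 and 3, 14 matrix genes and 10 protease genes fell. Of 23 TGF-beta and BMP targets 14 fell and 3 rose, over all genes and adjusted over the list alone. Ltbp2 and the inhibitory Smad6 (-1.17 ± 0.08) fell, and Tgfb2 (1.30 ± 0.11), Tgfbi (0.45 ± 0.11) and Id2 (0.23 ± 0.05) rose. Its camera test had an adjusted p of 0.000106, and adjusted p = 0.227 with an estimated correlation.

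Angiogenic factors split, with 15 of 31 lower and 7 higher (16 and 7 when adjusted over the list alone). Placental growth factor (Pgf) rose by 2.05 ± 0.06, while Ecm1 (-1.60 ± 0.14) and Adm (-0.81 ± 0.05) fell. The list was called lower (mean log2 difference -0.10, adjusted p = 0.0158), with adjusted p = 0.121 with an estimated correlation. Of 34 interferon response genes 10 fell and 0 rose, over all genes and adjusted over the list alone, including the RNA sensor gene Ddx58 (-0.54 ± 0.07) and Ifit2 (-0.53 ± 0.05). By camera the adjusted p was 0.0013, and adjusted p = 0.569 with an estimated correlation. The count was 6 without ASPSCR1-TFE3 array 3 or empty vector array 3, 18 without ASPSCR1-TFE3 array 2, 4 without empty vector arrays 2 and 3, and 16 without ASPSCR1-TFE3 arrays 2 and 3.

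Markers of cell types also differed. Of 39 skeletal muscle markers 30 rose and 2 fell (31 and 2 when adjusted over the list alone). The troponin genes Tnnt3 and Tnnc2 rose by 2.04 ± 0.14 and 1.88 ± 0.14, the perinatal myosin Myh8 by 1.98 ± 0.11 and the fast-fibre actinin Actn3 by 2.43 ± 0.08, although Actn3 did not pass under a variance trend over the mean deposited value (adjusted p = 0.165). In Actn3, Tnnt3, Tnnc2 and Myh8 the ASPSCR1-TFE3 means lay near 0, from -0.06 (Tnnt3) to 0.10 (Tnnc2). The empty vector means lay far below 0, from -2.47 (Actn3) to -1.79 (Tnnc2). For Aqp3 the ASPSCR1-TFE3 arrays were the ones far from 0. Since 0 also depends on arrays not analysed here, these values do not show which group had changed. Pax7 (-0.32 ± 0.10), a marker of muscle progenitors, and the myogenic factor Myod1 (-0.43 ± 0.12) fell. The set test returned an adjusted p = 9.7e-15, and adjusted p = 0.19 with an estimated correlation. Of 30 macrophage and myeloid markers 19 rose and 0 fell (20 and 0 when adjusted over the list alone), including Cd68 by 1.40 ± 0.07, lysozyme (Lyz2) by 1.40 ± 0.06 and Tyrobp by 1.38 ± 0.09. For the list as a whole the adjusted p was 3.6e-09, and adjusted p = 0.103 with an estimated correlation.

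Of 41 limb mesenchyme and connective tissue markers 19 fell and 0 rose (21 and 0 when adjusted over the list alone), with Cd34 at -1.53 ± 0.12, Osr1 at -1.13 ± 0.06 and Thy1 at -1.01 ± 0.09. The camera test of the list gave an adjusted p = 6.8e-07, and adjusted p = 0.121 with an estimated correlation. Of 28 endothelial markers 14 fell and 1 rose (14 and 2 when adjusted over the list alone), including Emcn (-0.80 ± 0.10) and Eng (-0.78 ± 0.07), and Vwf rose by 0.36 ± 0.07. The list passed camera with an adjusted p of 8.2e-05, and adjusted p = 0.122 with an estimated correlation. Of 23 keratinocyte and epithelial markers 10 fell and 1 rose, over all genes and adjusted over the list alone, with Krt18 at -1.36 ± 0.10 and Cldn4 at 0.77 ± 0.11. Its camera test had an adjusted p of 0.00847, and adjusted p = 0.121 with an estimated correlation, and 5 fell without empty vector arrays 2 and 3.

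**Figure D2:**
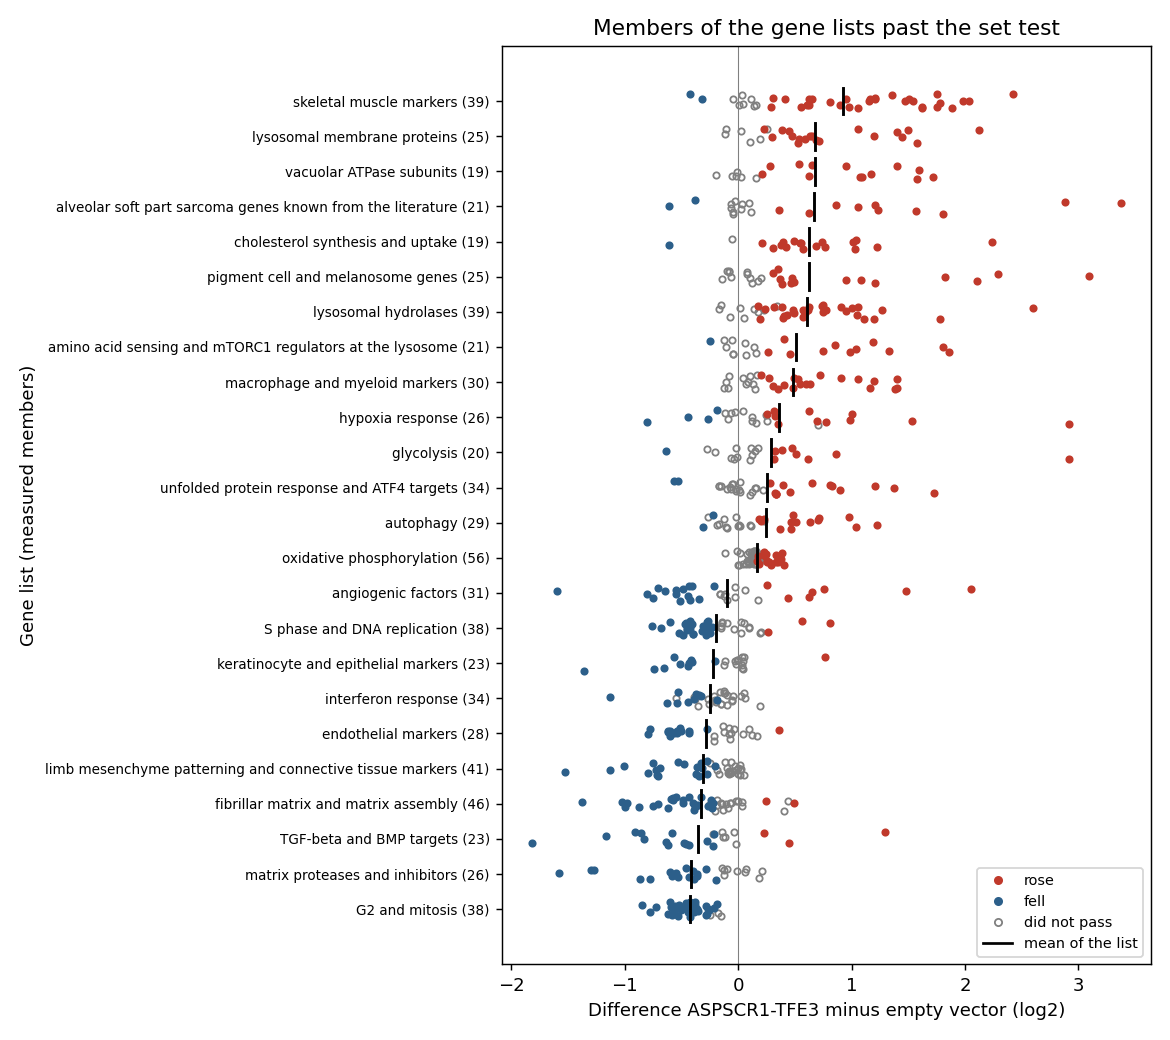
Log2 difference (ASPSCR1-TFE3 minus empty vector, 3 arrays each) of each measured member of the 24 gene lists past the set test, with filled points for genes that passed at an adjusted p under 0.05, open points for others and a bar at the mean of the list. Means run from -0.43 for G2 and mitosis to 0.92 for skeletal muscle markers.

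Spike-in controls differed between arrays. The median of the hybridisation controls was 0.90 and 0.78 on empty vector arrays 2 and 3, against 0.09 on empty vector array 1 and -0.18 to -0.01 on the ASPSCR1-TFE3 arrays. The poly-A controls stood at 0.82, 0.04 and -0.20 on ASPSCR1-TFE3 arrays 1 to 3 and at 1.29, 1.25 and 0.70 on the empty vector arrays. Without empty vector arrays 2 and 3, 1366 genes rose and 944 fell. Without ASPSCR1-TFE3 arrays 2 and 3 the counts were 1615 and 1081. Both leave 1 array in a group, which is then assumed to vary like the other group. With the hybridisation level as a covariate 11 cholesterol genes rose, and 11 limb mesenchyme markers and 9 fibrillar matrix genes fell. With the poly-A level as a covariate 6 TGF-beta and BMP targets fell.

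**Figure D3:**
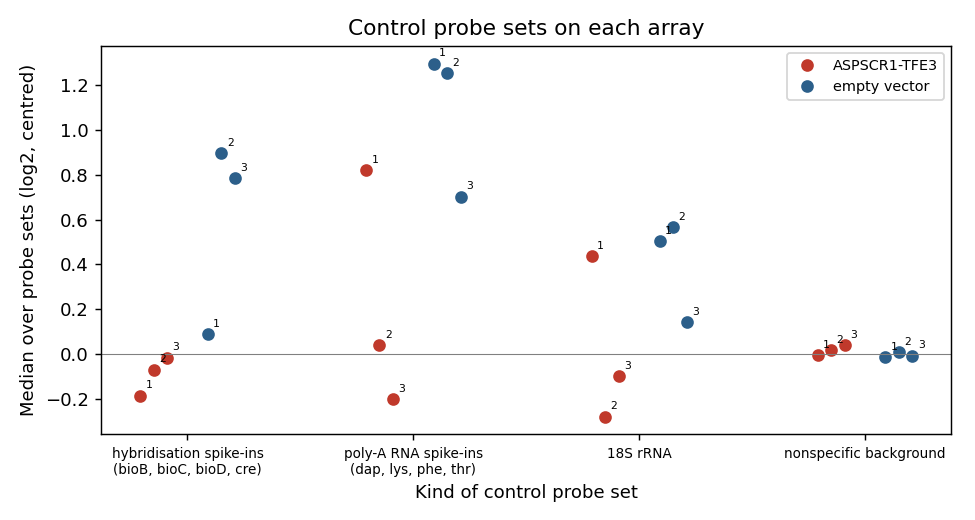
Median value (log2, centred) of 4 kinds of control probe sets on each array, with the replicate number beside each point. Hybridisation controls reach 0.90 and 0.78 on empty vector arrays 2 and 3, and nonspecific background probes lie near 0 on all 6 arrays.

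Of the 5047 called genes, 51.8% were higher with ASPSCR1-TFE3, and 61.9% after quantile normalisation (2752 higher and 1695 lower). The groups did not overlap in 7557 genes (44.2%), where chance gives 10% for any single gene. All genes share the same arrays, so the gap between these shares is no test of chance. With an estimated correlation 0 of the 41 lists passed camera, against 14 higher and 10 lower with the preset correlation. At an unadjusted p under 0.05 the estimated correlation gave 9 lists higher and 6 lower. With fry, which does not compare a list with other genes, the adjusted p was 8e-05 for the lysosomal hydrolases. It was over 0.05 for 2 of the 24 lists, oxidative phosphorylation (0.076) and interferon response (0.119). Several lists that camera did not call also had a fry adjusted p under 0.05. These were vesicle trafficking (0.0026), p53 (0.0035), bone (0.0041), tendon (0.0055), neural (0.0103), osteoclast (0.0128) and inflammatory (0.0295). A pass with fry therefore does not set the 24 lists apart.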

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

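The tests of explanations and the comparison of splits in this part were chosen after the results were seen, and the rules for muscle differentiation, the share of the main cell type, lysosomal genes among macrophage markers and the spike-in controls were replaced at least once with values in view (an earlier muscle rule, on genes picked because they rose, had favoured differentiation and was dropped). Of 16139 probe sets that name no single gene and so lie outside the comparison of genes, 994 rose and 2396 fell with ASPSCR1-TFE3 (limma, Benjamini-Hochberg adjusted p under 0.05). They are given because the gene comparison does not use them. They come from the same arrays and the same group comparison, so they are no independent support for the gene calls. Most of their calls were falls, whereas 2613 genes rose and 2434 fell. Quantile normalisation lowered the falls among genes to 1695, and the probe sets that name no single gene were not counted after it. How far their excess of falls depends on normalisation is therefore unknown. Over all 45037 probe sets that are no controls, 5023 rose and 6225 fell.

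Skeletal muscle markers rose in 30 of 39 cases (camera adjusted p = 9.7e-15, and adjusted p = 0.19 with an estimated correlation). In the markers with the largest rises, Actn3, Tnnt3, Myh8 and Tnnc2, the empty vector arrays lay far below 0 (means -2.47 to -1.79). The ASPSCR1-TFE3 arrays lay near it (means -0.06 to 0.10). More muscle lineage cells of every stage would raise the early markers Pax7, Myf5, Myod1, Cdh15 and Des alike, but 2 of these 5 had an upper 95% bound below 0 (Pax7 and Myod1). These 5 were chosen with their values in view, so the result cannot decide against that explanation, which stays open. A lower share of the main cell type would lower the limb mesenchyme markers, of which 19 of 41 fell, and raise those of every other type alike, but of the other 11 marker lists the endothelial (95% interval of the list mean -0.39 to -0.19, 3 arrays against 3) and epithelial (-0.29 to -0.15) moved apart from the macrophage list (0.41 to 0.55), and these 3 passed camera at the preset correlation but not at an estimated one (adjusted p = 0.122, 0.121 and 0.103). The interval also lay below 0 for bone and neural markers, 4 lists in all, and above 0 for lymphocyte and mast cell markers. These 3 did not pass camera (adjusted p = 0.125, 0.227 and 0.48), and in the last only Kit, Cpa3 and Cma1 of 17 rose. The level of each marker is unknown, and markers of a type absent from the culture could not rise. The rule was also replaced with values in view. The list means therefore cannot decide against a lower share of the main cell type, which stays open. Whether muscle cells had differentiated further stays open, because the 5 early markers were set apart after their values were seen, so that the gap of 1.07 between the median of the other 34 and theirs restates the pattern and is no support, Myf5 rose by 0.81, and expression of muscle genes in other cells of the culture was not tested.

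Macrophage and myeloid markers rose in 19 of 30 cases (adjusted p = 0.103 with an estimated correlation). The markers that are also in a lysosomal list, Cd68 and Ctss, do not account for all of this. The 28 markers in no lysosomal list had a mean log2 difference of 0.42 (95% interval 0.35 to 0.49 over 3 arrays against 3). Their unadjusted camera p was 1.8e-08, and with an estimated correlation camera gave an unadjusted p = 0.0199 and an adjusted p = 0.117. Lysosomal genes that those lists do not hold may remain among the 28, so a wider lysosomal explanation stays open. Of these 28, 17 rose and 0 fell, led by Lyz2 (1.40) and Tyrobp (1.38), while Csf1r (-0.09), Aif1 (0.10) and Cd14 (0.07) did not pass. More macrophages in the ASPSCR1-TFE3 cultures and expression of these genes in mesenchymal cells may both give this, and cannot be told apart because the centring removed the level of each marker.

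Many genes were called while the spike-in controls differed between arrays, and if either control made the calls, 2 arrays with alike levels of it would show little of the difference found in the other 4, and with no change the ratio of the 2 differences would centre on 0. In the pair closest in hybridisation controls (ASPSCR1-TFE3 array 3 and empty vector array 1) the spike-ins kept 0.11 of their difference, while 3597 genes called in the other 4 arrays kept a median of 0.80 (quartiles 0.53 and 1.03), and in the pair closest in poly-A controls (ASPSCR1-TFE3 array 1 and empty vector array 3) the spike-ins kept -0.09 and 3799 genes a median of 0.81 (0.52 and 1.07). Each of these pairs stood apart on the other control (poly-A ratio 2.74 and hybridisation ratio 1.81), and in the pair low on both (the 2 arrays numbered 1, ratios 0.31 and 0.45) 4921 genes kept a median of 0.78 (quartiles 0.46 and 1.04). These values speak against either spike-in difference alone as the whole cause, but each rests on 1 pair of arrays, and both differences together, or a part of the count, stay open. An effect of ASPSCR1-TFE3 itself is the biological explanation that the design gives, and it remains a hypothesis about the pattern of calls.

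The real split of the 6 arrays gave 2613 genes higher and 2434 lower, and the highest of the other splits gave 0 with limma (78 to 521 genes in all at an unadjusted p under 0.05, against 6767 in the real split). For both counts 1 of the 10 splits gave as many genes, the real one itself, and 10 splits are too few for a share under 0.05. Each other split puts arrays of both groups on both sides, so any group difference widens the spread within a side and holds its calls down. The contrast with the real split is therefore no measure of chance.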

How the results depend on the processing

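Alternatives with the spike-in controls, the probe sets tested alone and the trend over the mean deposited value were chosen after seeing the data, and the others were planned. The counts of genes and lists stayed within 1.5 times their values under quantile normalisation, centring on array medians, probe sets without the _x and _s kinds, robust variance, array weights and the trend (2670 higher and 2542 lower). They moved further in these cases. At least a 2-fold difference left 432 genes higher and 73 lower, and an estimated correlation left 0 lists higher and 0 lower. Without empty vector arrays 2 and 3 there were 1366 and 944 genes, of which 1342 and 911 were among those called with all arrays. Without ASPSCR1-TFE3 arrays 2 and 3 there were 1615 and 1081 (1571 and 990 shared), with the poly-A covariate 1497 and 990 (1457 and 910), and with the hybridisation covariate 1296 and 935 (1227 and 851). Fewer arrays or residual degrees of freedom lower such counts by construction, and the cause was not tested further. Leaving out 1 array at a time gave 2100 to 2603 genes higher and 1686 to 2392 lower, with 13 to 17 lists higher and 10 to 11 lower. Same-numbered arrays of the 2 groups had deviations correlated at 0.11, -0.27 and 0.02, against -0.25 to 0.25 for other pairs. Not every array correlated best with its own number. The deviations are from means of only 3 arrays, so they cannot show whether equal numbers share an embryo, litter or day. The labels do not say. With the replicate block 2390 genes were higher and 2118 lower. Of 170 named genes 166 were called. None reversed its direction under the alternatives run while called in the main fit or in the alternative. Changes of sign in genes called in neither were not counted. Calls were lost by 25 named genes with the hybridisation covariate and by 24 with the poly-A covariate. Up to 6 lost their call under any other alternative that kept at least 2 arrays in each group. Adding 16 before the logarithm and the stricter filter on dim genes were not run, because the deposited values carry no level, and signal over background is unknown.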

Other observations

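The 4 lists of this paragraph were written, and their tests chosen, after the values were seen. Of 21 genes induced by ERK signalling 15 fell and 1 rose, including Ereg, Fosl1 (-1.20 ± 0.15, log2 difference ± SE), Errfi1 (-1.14 ± 0.06), Myc (-1.10 ± 0.06) and Ccnd1 (-0.97 ± 0.10), while the ERK phosphatase gene Dusp4 rose by 1.88 ± 0.10. Circadian clock genes rose in 9 of 19 cases and fell in 3, with Cry1 higher by 2.10 ± 0.12, Ciart by 1.91 ± 0.13 and Dbp by 1.41 ± 0.06, and Nfil3 (-0.45 ± 0.08), Arntl (-0.34 ± 0.07) and Csnk1d (-0.31 ± 0.05) lower. Of 18 cytoskeletal target genes of YAP and SRF 10 fell and 1 rose, with filamin A (Flna) at -1.06 ± 0.10, Myh9 at -0.99 ± 0.16 and F3 at 0.29 ± 0.09. Of 8 aryl hydrocarbon receptor targets 5 fell and 1 rose, with Cyp1a1 at -1.54 ± 0.13 and Tiparp at 0.63 ± 0.07. Camera, adjusted over these 4 lists alone, gave adjusted p-values from 6.1e-08 to 0.00705, and adjusted p = 0.0932 for each with an estimated correlation. Those values cannot be set beside the ones of the fixed lists. They are no independent support, because the lists were written with the values in view.

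The other fixed lists did not pass camera (adjusted p from 0.0624 to 0.863), though the vesicle trafficking, inflammatory, p53, ribosomal, mitochondrial biogenesis and adipocyte lists passed under at least 1 alternative (lowest adjusted p = 0.033, 0.0326, 0.0427, 0.0305, 0.028 and 0.00877). Inflammatory cytokines and chemokines went both ways, with 8 of 36 higher and 14 lower (8 and 15 when adjusted over the list alone), Cxcl16 higher by 1.91 ± 0.06 and Cxcl1 lower (-1.62 ± 0.07). In vesicle trafficking 10 of 35 rose and 1 fell, with the same counts adjusted over the list alone. Stx11 rose by 1.36 ± 0.15, and Rab27a by 1.24 ± 0.05 over 4 probe sets that disagreed (3.36, 1.00, 0.59 and -0.00). Among p53 target genes 3 of 24 rose and 10 fell, and in the oxidative stress response 5 of 24 rose and 7 fell (6 and 7 when adjusted over the list alone), with Nqo1 at -1.14 ± 0.10. Regulators of mitochondrial biogenesis and fatty acid oxidation had 5 higher and 1 lower of 22 (6 and 1 when adjusted over the list alone), with Cpt1a at 1.09 ± 0.12 and Pdk4 at -1.33 ± 0.12. Wnt signalling had 5 higher and 6 lower of 31, and cytosolic ribosomal proteins 0 and 1 of 43 (0 and 0 when adjusted over the list alone).

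Tendon markers had 3 higher and 6 lower of 12 (4 and 6 when adjusted over the list alone), with Tnmd at 1.19 ± 0.13 and Thbs4 at -1.38 ± 0.06. Cartilage markers had 5 and 6 of 22, bone markers 0 and 1 of 12, and adipocyte markers 6 and 1 of 21 (8 and 2 when adjusted over the list alone). Smooth muscle contractile genes had 5 higher and 7 lower of 20 (5 and 8 when adjusted over the list alone). Osteoclast markers had 4 and 1 of 11, with Ctsk at 1.06 ± 0.08 and Mmp9 at -1.58 ± 0.14, and markers of neural crest, Schwann cells and neurons 3 and 2 of 19, with Stmn2 at -1.53 ± 0.07. Lymphocyte and mast cell markers had 3 higher (Kit, Cpa3 and Cma1, of which Cpa3 and Cma1 did not pass with either spike-in covariate) and 0 lower of 17, and erythroid markers 0 and 1 of 11. Where no second pair is given, the counts adjusted over the list alone were the same.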
